A study of Mus musculus with 2 samples.

How the data were processed

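DNase-seq of whole mouse embryos of 11 days gave a peak list and a hotspot list for each of 2 biological replicates. Per the labels, both came from pooled male and female embryos of the B6NCrl strain, with a separate biosample entry each and a shared donor entry. Per the file headers and accompanying text, each list was made by the submitters from the filtered mm10 alignments of its own replicate, so replicates were not pooled and each list measures what was called in 1 library. The aligner, the caller, their versions and the read filters are not given in the sources used here. Deposited peaks are 150 bp wide, apart from 1 of 141 bp on a scaffold, and carry a score, a whole number from 1 to 150 whose construction is not given in the sources used here. It was used to rank or filter peaks within a list, to relate both replicates over shared peaks and to compare medians between sets of peaks of 1 list. Its zero point is unknown, so a ratio of scores is no ratio of signal. Deposited hotspots carry a value that their file format defines as the −log10 of a q value. It starts at 1.30 and stops at a ceiling of 100, which 33.3% and 34.1% of hotspots had, so hotspots at the ceiling could not be ranked among themselves. All peaks overlapped a hotspot of their own replicate by at least 1 bp. Read counts are not given, so the depth is unknown, and a longer list in replicate 2 can come from depth, from the library or from the embryos.

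The reference was the GRCm38 (mm10) sequence and the GENCODE M21 annotation, which matched the build of the files. Gene measures used 21728 protein-coding genes on chromosomes 1 to 19 and X, and feature classes also used chromosome Y. Peaks on scaffolds or the mitochondrial genome entered the list totals, the overlap and the score measures of shared and unshared peaks. They also entered the choice of better-scoring peaks and the counts of the closing section, but were not themselves part of any gene measure or feature class. The ranking from which the best-ranked peaks were named left them out too. A peak was shared when it overlapped a peak of the other replicate by at least 1 bp, and the shared set consists of the replicate 1 peaks that did so. Expected overlap came from 100 circular shifts of 1 list within each chromosome, which keep the spacing of peaks. Each peak was assigned by its midpoint to a promoter (within 500 bp of a protein-coding TSS), else an exon, else an intron, else the space between genes. A gene had a promoter peak when a peak came within 500 bp of any of its annotated TSSs. Distal peaks lay more than 1 kb from every protein-coding TSS and were counted per territory, the bases nearer to the 5'-most TSS of a gene than to that of any other protein-coding gene, per 100 kb of assembled sequence. Repeats were the lower-case bases of the reference. Intron numbers follow the principal transcript of each gene.

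The 25 gene lists, the motifs, the tests and the rule for the genes named were fixed before the data were examined. The lists cover neural progenitors, differentiating neurons, neural crest, somite and muscle, limb bud, heart, endothelium, erythroid cells, hepatoblasts, gut and pancreas, kidney and gonad, cartilage and mesenchyme, surface ectoderm, macrophages, lymphocytes, pluripotency and germ cells, trophoblast and decidua, yolk sac, adult organs, spermatids, olfactory and vomeronasal receptors, Hox clusters, signalling, imprinted genes and housekeeping. Some genes stand in more than 1 list, so the lists are not independent. Of the 17 erythroid genes, 16 were found in the annotation, and all members of the other lists were found. Named genes are up to 4 members of each list with and up to 3 without a promoter peak in both replicates, in list order. Added to these are the 10 genes with the most distal peaks, the 10 with the highest distal density among territories of at least 100 kb, the genes at the 10 widest intersections of hotspots and at the 10 best-ranked peaks, 16 landmark genes, and the discordant members of any list that differed between replicates. Some genes and regions that this rule selects are not reported here. For the receptor list, which differed under 1 setting only, counts are given in place of names.

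Promoter peaks of lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes. Distal density was tested as the list median against 10000 random lists (1000 for the receptor list) of the same size matched on decile of territory length, a two-sided permutation test in which random lists could include members. Replicates were compared per list with an exact binomial test on promoters seen in 1 replicate only and with Fisher's exact test against all other genes. Motifs were 18 consensus sequences searched on both strands in distal peaks and in windows of 150 bp at 1 kb to either side that held no peak, tested by an exact binomial test on discordant pairs. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. Chromosome densities have no test. Shares of peaks have Wilson 95% intervals, which cover counting error only. With 1 group, no effect between groups and no regrouping of samples could be tested.

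Alternatives were a reciprocal overlap of 50%, the better-scoring 50% of each list, equal list lengths, autosomes only, promoter windows of 1000 and 2500 bp, all annotated genes, the 5'-most TSS alone, hotspots in place of peaks, other backgrounds, a distal distance of 5 kb, a fixed window of 100 kb to either side of the TSS, list means, other flanks, the reversed consensus and each replicate alone. A match on territory length and promoter CpG quintile together was added after seeing the data.

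The statistics were tested on simulated data. For the overlap of lists, with 200000 simulated peaks per list, 70.1% were planted as shared and 70.8% recovered, against 2.21% after shifts. For promoter peaks over 21728 genes, 98.0% of lists with a planted rise, 96.7% with a planted fall and 0.5% of unchanged lists were called. For distal density, 100% of lists with doubled density and 2.35% of the others were called. Simulated distal counts were Poisson counts around a single base density, planted promoter changes were large, and simulated promoters ignored CpG content. These rates therefore need not hold for the real lists. In the real data erythroid genes, at a median of 5.08 against 1.96 in random lists, were not called. For motifs, 5.3% of 20000 windows were given a site, 5.35% were found to have one, and 0.04% of windows without a planted site had one. For the comparison of replicates by list, with most members of a changed list planted as seen in 1 replicate only, 85.0% of changed lists and 0% of the others were called. That effect is far larger than any the lists of this series showed. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.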

Results

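Accessible chromatin was measured by DNase-seq in whole mouse embryos of 11 days. In this assay the enzyme DNase I cleaves DNA where nucleosomes do not shield it, and the cleaved ends are sequenced. The samples form 1 group with 2 biological replicates, each made from pooled male and female embryos of the B6NCrl strain. There was no other stage, tissue or treatment, so the comparisons are between the replicates, between gene groups and between parts of the genome. Replicate 1 had 204697 peaks covering 30.3 Mb (1.14% of the assembled bases) and replicate 2 had 231103 covering 34.2 Mb (1.29%). Hotspots, the broader regions of enriched cleavage, numbered 179603 over 61.9 Mb and 197152 over 73.1 Mb. The read depth of each library is unknown, because the files used here hold intervals and not reads. Every test over genes or peaks describes these 2 libraries, since genes and peaks are not replicates.

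On the assembled nuclear chromosomes, the highest-ranked peaks found in both replicates lay at promoters. The 10 with the best mean rank of the deposited score were nearest to Lmnb1 (a nuclear lamina protein), Stag1 (a cohesin subunit), Fam76a, Cdkn2d (a cell cycle inhibitor), Hjurp (a centromere chaperone), 9430015G10Rik, Rbbp4 (a histone-binding protein), Pigm, Mex3c and Bcl9. All of these 10 lay within 473 bp of an annotated protein-coding transcription start site (TSS). The peak at Stag1, on chromosome 9 from 100643296 to 100643445 (mm10), scored 148 in replicate 1 and 149 in replicate 2 on a scale that ended at 150. Peaks on the mitochondrial genome were left out of this ranking. All 26 mitochondrial peaks of replicate 1 were shared, and 10 of them had the top score of 150 in that replicate.

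The widest regions where hotspots of both replicates intersected spanned several kb each. The widest was 8514 bp at Tnrc18, on chromosome 5 from 142815995 to 142824508, and held 17 peaks found in both replicates. Others were at Tgif1 (6104 bp), Marcks (5937 bp), the cyclin gene Ccnd1 (5123 bp), the axon guidance gene Efna5 (5054 bp), Brd2 with H2-DMa (4907 bp), Patz1 (4821 bp) and Zmiz1 (4816 bp). A region of 5237 bp on chromosome 3 (34660438 to 34665674) overlapped no protein-coding gene. It lay 12651 bp from the TSS of Sox2, a transcription factor of neural progenitors, and held 7 shared peaks.

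The first comparison asked how far both libraries found the same sites. Of the replicate 1 peaks, 162667 (79.5%, Wilson 95% interval 79.3 to 79.6) overlapped a replicate 2 peak by at least 1 bp. In the other direction the share was 162358 peaks (70.3%, 70.1 to 70.4). Over both directions this was 74.9% ± 6.52 (SD, n = 2). That SD compares 2 directions of 1 overlap with nearly equal shared counts. It therefore reflects mainly the unequal list lengths and is no spread of independent measurements. Circular shifts of 1 list within each chromosome gave on average 2.73% and 2.42%, so the overlap was 29.2-fold and 29.1-fold above the shifts. No shift reached the observed value (one-sided permutation p = 0.0099, the smallest that 100 shifts allow). Hotspots were shared at 82.1% and 70.8% (76.4% ± 8.05, SD of both directions, n = 2). Shifts gave 5.26% and 4.76% (one-sided permutation p = 0.0099, again the smallest possible). The covered bases had a Jaccard index of 0.466 for peaks and 0.666 for hotspots. Over the 162667 shared peaks the scores of both replicates had a Spearman rho of 0.938, a correlation across peaks within 1 pair of libraries.

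Peaks found in 1 replicate only were low in score. In replicate 1 the median score was 30 for its 42030 unshared peaks and 51 for shared ones, and in replicate 2 it was 35 for 68745 unshared peaks and 61 for shared ones. The shared percentage rose with each decile of score, from 41.0% to 98.8% in replicate 1 and from 27.3% to 98.3% in replicate 2. Unshared peaks were less often at promoters, with 9.20% in replicate 1 and 7.48% in replicate 2 against 17.0% of shared peaks. Their mean GC content was 51.0% and 50.5%, against 54.1% in shared peaks, and 5.46% and 6.0% consisted mostly of repeats, against 3.81% and 3.78%. Hotspots of the other replicate were found at 22.9% of the unshared peaks of replicate 1 and at 11.2% of those of replicate 2.

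**Figure D1:**
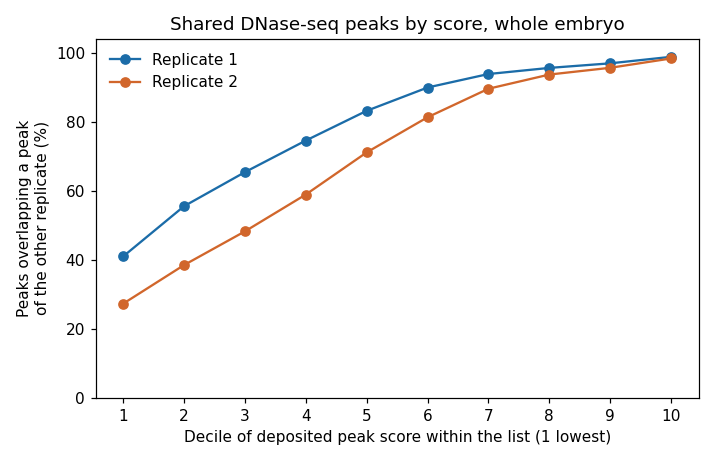
Percentage of peaks that overlap a peak of the other replicate (vertical axis) in each decile of the deposited score (horizontal axis, 1 lowest), with 1 line per replicate. The percentage rises from 41.0% to 98.8% in replicate 1 and from 27.3% to 98.3% in replicate 2.

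Shared peaks were concentrated at promoters of protein-coding genes. Of 162506 shared peaks on the assembled chromosomes, 17.0% had their midpoint within 500 bp of a protein-coding TSS, where 2.02% of bases lie, an 8.42-fold excess. Exons held 4.48% of the peaks (2.91% of bases), introns 35.4% (34.6%) and the space between genes 43.2% (60.4%). Circular shifts gave 2.18% at promoters, so the observed share was 7.81-fold higher (one-sided permutation p = 0.0099, the smallest possible). The intron share lay close to its shifted mean of 36.4% (one-sided permutation p = 0.0198, not adjusted for the 4 classes), and the intergenic share lay below its shifted mean of 58.3% (one-sided permutation p = 0.0099, the smallest possible). In each class the p was taken on the side where the observed share lay, so a two-sided p would be larger. All peaks of replicate 1 gave a promoter share of 15.4% and those of replicate 2 gave 14.2%. The share depended on what counted as a promoter, reaching 29.9% with a window of 2500 bp. That window covers 8.03% of bases, so the excess was then smaller, at 3.72-fold. The share within 500 bp was 26.0% among the better-scoring 50% of each list.

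At the level of genes, 15275 of 21728 protein-coding genes on chromosomes 1 to 19 and X (70.3%) had a promoter peak in both replicates. Another 190 had one in replicate 1 only, 390 in replicate 2 only and 5873 in neither. Promoter sequence separated these genes strongly. In the lowest decile of the observed-to-expected ratio of CpG dinucleotides 8.93% of genes had a shared promoter peak, and in the highest decile 99.4% had one.

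Gene lists fixed before the data were examined showed which promoters had a peak in these whole-embryo libraries. A promoter without a peak was not called in this mixture of tissues, and is not shown to be closed in every cell type. Every member had a promoter peak in both replicates in the lists for differentiating neurons (18 of 18 genes, among them Tubb3, Elavl3, Elavl4 and Dcx), the limb bud (17 of 17, among them Tbx5, Tbx4, Pitx1 and Fgf8), the kidney and gonad (14 of 14, among them Pax2, Pax8, Osr1 and Wt1), cartilage and mesenchyme (16 of 16, among them Sox9, Sox5, Sox6 and Col2a1) and housekeeping functions (16 of 16, among them Actb, Gapdh, Hprt and Pgk1). The neural progenitor list had 17 of 18, with Sox1, Sox2, Sox3 and Pax6 among them. Nkx2-2, a ventral neural tube gene, had one in replicate 2 only. The signalling list had 20 of 21, with Shh, Bmp2, Bmp4 and Bmp7 among them, and Wnt3a had one in replicate 2 only. Of the 39 Hox genes, which set position along the body axis, 35 had a shared promoter peak, and Hoxc11, Hoxc9 and Hoxd12 were among those that did not.

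These 8 lists had a promoter peak more often than other genes, of which 70.3% had one (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over 25 lists). The adjusted p was 0.0140 for differentiating neurons, 0.0151 for the limb bud, cartilage and housekeeping lists, 0.0171 for the Hox and signalling lists, 0.0286 for kidney and gonad and 0.0369 for neural progenitors. When random genes matched on promoter CpG decile served as background, 0 lists were called more often. The neuron, limb bud, kidney, cartilage and housekeeping lists were already at 100%, so their permutation p was the smallest the match allowed. Unadjusted, that permutation p ran from 0.0218 for cartilage to 0.327 for the limb bud, so the missing calls of these lists tell little. The smallest adjusted permutation p among the 8 was 0.142, for the neuron and cartilage lists. Most still had a higher share than their matched genes, by 18.8 percentage points for cartilage, 16.7 for neurons, 14.3 for kidney and gonad, 12.5 for housekeeping, 5.88 for the limb bud and 4.76 for signalling, while neural progenitors were level (0) and Hox genes lower (-2.56). The neuron, cartilage and housekeeping lists kept their call under every other setting tried, while the remaining lists each lost it under at least 1, such as the use of the 5'-most TSS alone or a background without chemoreceptor genes, which left 4 lists each.

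Genes of adult organs, sperm, immune cells and the placenta seldom had promoter peaks. In the adult organ list only 3 of 18 genes (Cela1, Gnat1 and Krt86) had one in both replicates, while Cpa1 (a pancreatic enzyme), Ctrb1 and Pnlip did not (adjusted p = 4.69e-05, Fisher's exact test). The spermatid list had 3 of 14 (Prm1, Spata18 and Izumo1), without Prm2, Tnp1 and Tnp2 (adjusted exact p = 0.00139). Tnp2 had a peak in replicate 1 only. The macrophage list had 2 of 13 (Adgre1 and Cd68), without the receptor genes Csf1r and Cx3cr1 or the regulator Spi1 (adjusted exact p = 0.000544). The lymphocyte list had 5 of 15 (among them Pax5, Rag1, Lck and Zap70), without Cd3e, Cd3d and Cd4 (adjusted exact p = 0.0140). It lost its call with a promoter window of 2500 bp (adjusted exact p = 0.0917). Cd3d had a peak in replicate 1 only. Pax5 also acts in the midbrain. The trophoblast and decidua list had 5 of 14, with Prl3b1, Ascl2, Elf5 and Hand1 among them and the placental genes Prl3d1, Prl8a2 and Prl2c2 without (adjusted exact p = 0.0171).

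Olfactory and vomeronasal receptor genes, which sensory neurons of the nose express, had shared promoter peaks in 29 of 1464 cases (1.98%), against 75.2% of other genes. Either replicate alone gave 3.28% for the receptor list. Replicate 2 alone raised the macrophage share from 15.4% to 30.8% and the adult organ share from 16.7% to 27.8%, and replicate 1 alone left both unchanged. Erythroid genes were below other genes too, with 7 of 16 (adjusted exact p = 0.0459). Klf1 and Tal1, which drive red cell formation, and the receptor gene Epor had a peak, while Gata1 had one in replicate 2 only, Hba-x, an embryonic globin gene, in replicate 1 only and Hba-a1 in neither. The erythroid call was lost when either replicate was used alone, with the 5'-most TSS alone and with a window of 2500 bp, which left 5 of the 7 lists called less often. Under CpG matching only the receptor list was still called less often (-15.0 percentage points, adjusted permutation p = 0.04995). Its unadjusted permutation p of 0.001998 is the smallest that 1000 random lists allow, and those lists could include receptor genes. Macrophage (-23.1), spermatid (-21.4), lymphocyte (-20) and adult organ genes (-16.7) were also below their matched values but not called, and erythroid and trophoblast genes were then 12.5 and 7.14 percentage points above their matched values.

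No call was made by the exact test for promoters of the other lists. The counts were 13 of 14 for neural crest, with Sox10, Foxd3, Tfap2a and Tfap2b (adjusted exact p = 0.117), and 15 of 18 for somite and skeletal muscle, with Myf5, Myod1, Myog and Pax3 and without Myf6, Tbx6 and Chrna1 (0.402). Heart genes also had 15 of 18, with Nkx2-5, Gata4, Tbx5 and Tbx20 and without Myh6, Myl7 and Nppa (0.402). Endothelium had 10 of 15, with Kdr, Tie1, Fli1 and Sox17 and without Cdh5, Pecam1 and Tek (0.824). Hepatoblast genes had 11 of 16, with Afp, Hnf4a, Foxa1 and Foxa2 and without Alb, Ttr and Apoa1 (1). Gut and pancreas endoderm had 12 of 16, with Pdx1, Sox17, Nkx2-1 and Sox9 and without Ptf1a, Cdx1 and Cdx2 (0.824). Surface ectoderm had 12 of 15, with Trp63, Krt8, Krt18 and Tfap2a and without the keratins Krt5, Krt14 and Krt15 (0.685). Pluripotency and germ cell genes had 10 of 15, with Esrrb, Tdgf1, Klf4 and Prdm14 and without Pou5f1, Nanog and Zfp42 (0.824). Yolk sac genes had 8 of 14, with Afp, Apob, Cubn and Amn and without Ttr, Apoa1 and Apoa4 (0.473). Imprinted genes had 15 of 16, with Igf2, Igf2r, Peg3 and Mest and without only Ndn (0.0806). Of the genes named here as without, Tbx6, Pecam1, Cdx2 and Krt5 had a promoter peak in replicate 1 only. Nppa, Cdh5, Ptf1a and Nanog had one in replicate 2 only. Against CpG-matched genes heart was 27.8 percentage points higher (adjusted permutation p = 0.0600), imprinted genes 18.8 higher (0.142) and neural crest 14.3 higher (0.192), gut and pancreas genes were at -18.8 (0.192) and pluripotency genes at -13.3 (0.321), none called, and the others were level. Other settings called some of these. Imprinted genes were above the background with a promoter window of 2500 bp (adjusted exact p = 0.0364) and in the better-scoring 50% of peaks (0.0460), where yolk sac genes were below it (adjusted exact p = 0.00232).

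**Figure D2:**
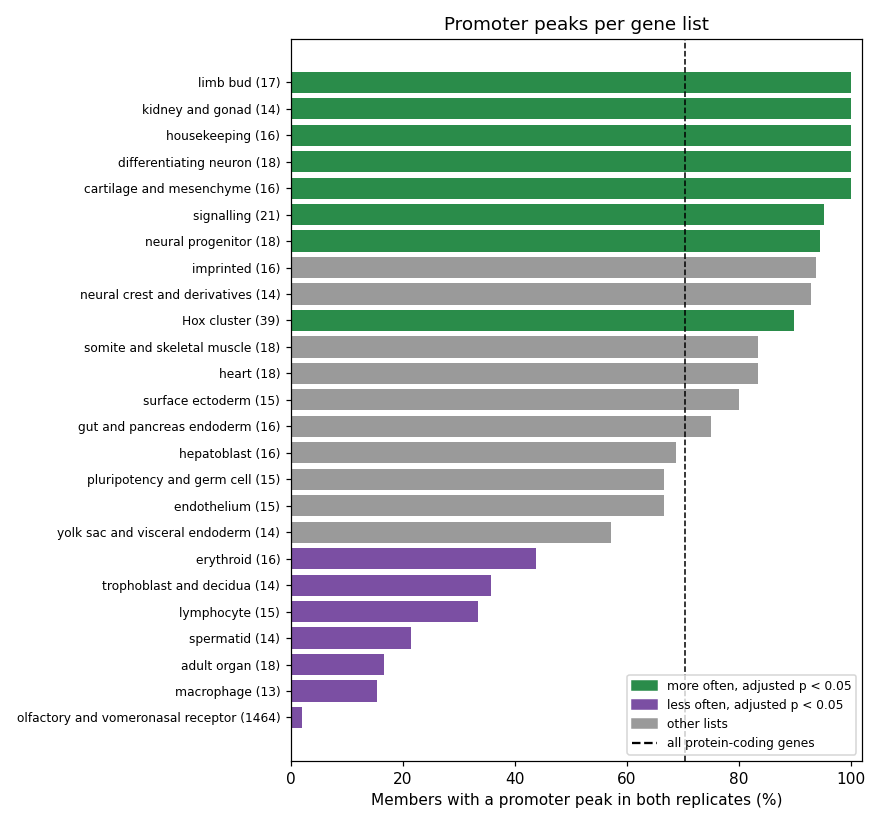
Percentage of each list's members with a promoter peak in both replicates (horizontal bars, with the number of members in brackets), coloured by Fisher's exact test, and the dashed line at 70.3% for all protein-coding genes. The 8 lists called more often reach 89.7% to 100%, and the 7 called less often reach 1.98% to 43.8%.

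Away from promoters, the number of peaks differed widely between genes. The territory of a gene is the sequence nearer to its 5'-most TSS than to that of any other protein-coding gene. The territory of Zfp608 held 199 shared peaks more than 1 kb from every TSS, more than any other gene. It was followed by Nr2f2 (153), a nuclear receptor of the mesenchyme, Lrmda (138), Zfp36l1 (131), Adgrl2, Sox9 and Zfhx3 (129 each), Meis1 (121), Robo1 (113) and Efna5 (108). These counts also reflect territory length. Adgrl2, Robo1 and Efna5, with territories of 2293, 2049 and 2243 kb, had 5.63, 5.52 and 4.81 distal peaks per 100 kb. The genome density was 4.90, and the other genes named here had 10.1 to 27.2. Among the 5857 territories of at least 100 kb, the densest was that of Uncx, a somite gene, with 40.5 distal peaks per 100 kb. Next came 1700001O22Rik (34.8), Gins2 (31.0), the neural gene Sox1 (28.6), the muscle and spinal cord gene Lbx1 (28.2), Zfp36l1 (27.2), Tnrc18 (26.6), Gse1 (25.7), Irf2bpl (25.4) and Smug1 (25.4). All protein-coding genes had a median of 4.12, and 125474 of the shared peaks (77.2%) were distal.

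Of the 25 lists, 13 had more distal peaks and 2 fewer than random lists of the same size and territory length. Values of the first 2 members with a promoter peak, in list order, are given beside the medians. Hox genes had the highest median, 20.7 per 100 kb, with Hoxb13 at 18.9 and Hoxb9 at 57.1. Limb bud genes had a median of 13.5 (Tbx5 13.5, Tbx4 19.4), neural progenitor genes 13.1 (Sox1 28.6, Sox2 11.6), somite and muscle genes 12.9 (Myf5 4.48, Myod1 14.1), signalling genes 10.7 (Shh 4.32, Bmp2 6.59) and kidney and gonad genes 10.6 (Pax2 22.3, Pax8 10.6). Each of these had an adjusted p of 0.000833 (two-sided permutation test, 10000 random lists), from an unadjusted 0.0002 that is the smallest these lists allow. Random lists of their territory lengths had medians from 4.41 to 4.84, except 0 for the Hox genes, whose territories are short.

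Distal peaks were also denser in the lists for cartilage and mesenchyme (median 10.4, with Sox9 at 10.1 and Sox5 at 9.74, adjusted permutation p = 0.00143), housekeeping (10.1, adjusted p = 0.0115), imprinted genes (9.41, 0.0115), heart (8.88, 0.0142), differentiating neurons (8.69, 0.0142), gut and pancreas (8.82, 0.0225) and neural crest (7.86, 0.0443). Trophoblast genes had a median of 0, below their random lists at 4.65 (adjusted permutation p = 0.0146), and receptor genes had a median of 0 against 3.60 (adjusted permutation p = 0.00624, 1000 random lists). The calls for neural progenitor, somite, limb, kidney, cartilage and signalling lists held under every setting tried. With distal set at more than 5 kb the lists for neurons, heart, Hox, imprinted and housekeeping genes lost their calls. In fixed windows of 100 kb to either side the calls for neurons (adjusted permutation p = 0.0900), neural crest and housekeeping (0.0771 each) were lost. List means lost neural crest (adjusted permutation p = 0.141) and trophoblast (0.0753), and the better-scoring 50% of peaks lost heart (0.0953). Neural crest lost its call without replicate 2, and trophoblast lost its call without replicate 1. Matching on territory length and CpG content together, chosen after seeing the data, lost neural crest and gut. Beyond 5 kb, in the better-scoring 50% and under that match, trophoblast and receptor genes were not called lower, but their random lists there reached a median of 0, so no lower call was possible. Hox genes beyond 5 kb had a median of 0, as did their random lists.

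No call was made for endothelium (median 7.20, adjusted permutation p = 0.171), surface ectoderm (8.37, 0.0662), erythroid (5.08, 0.375), hepatoblast (4.49, 0.848), macrophage (5.84, 0.584), lymphocyte (5.23, 0.634), yolk sac (5.69, 0.634), pluripotency (4.51, 0.992), adult organ (4.59, 0.833) or spermatid genes (0, 0.617). Macrophage and adult organ genes, which seldom had promoter peaks, had medians above those of their random lists, 3.75 and 4.01, by less than the spread of those lists. Random lists for spermatid, erythroid, macrophage, lymphocyte and adult organ genes reached medians of 0, so these lists could not have been called lower. Surface ectoderm gained a call in the better-scoring 50% and with either replicate alone, and endothelium gained one beyond 5 kb and without replicate 1.

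**Figure D3:**
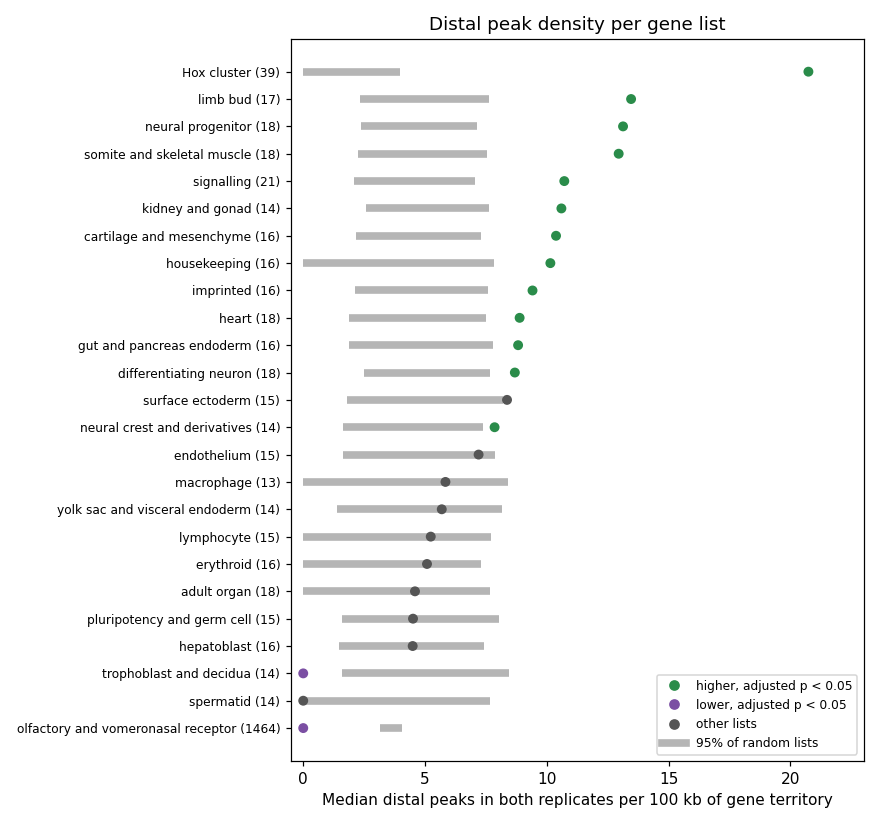
Median number of distal peaks found in both replicates per 100 kb of gene territory for each list (points, with the number of members in brackets) and the range holding 95% of the medians of random lists of the same size and territory length (grey bars). Hox genes reach 20.7 and limb bud genes 13.5, while trophoblast, spermatid and receptor genes have a median of 0.

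Landmark genes with known embryonic enhancers were examined peak by peak in mm10 coordinates. Lmbr1, on chromosome 5 from 29229802 to 29378390, holds in its intron 5 the limb enhancer of Shh, and that intron had 2 shared peaks, at 29293316 to 29293465 (scores 75 and 83) and at 29314716 to 29314865 (43 and 47). A peak in its intron 4, at 29335956 to 29336105 (scores 54 and 64), carried a match to the CTCF consensus. Its reference sequence, 40.0% GC, was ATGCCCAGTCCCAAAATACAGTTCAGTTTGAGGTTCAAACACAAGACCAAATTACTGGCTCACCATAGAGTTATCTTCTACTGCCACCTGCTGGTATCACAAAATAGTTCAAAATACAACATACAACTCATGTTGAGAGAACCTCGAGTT. Shh itself had 10 shared peaks in its gene body and 19 distal peaks over a territory of 439 kb. Sox2 had 97 distal peaks over 836 kb, Sox9 had 129 over 1277 kb, and Pax6, the eye and neural tube gene, had 29 over 253 kb. The gene body of Pax6 held 15 of the 40 shared peaks in its territory. The muscle gene Myf5 and the heart gene Nkx2-5 had 5 distal peaks each, and Hoxd13 had 2 shared peaks in its territory, both at its promoter.

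Landmark genes of blood, liver, heart and pluripotency were examined in the same way. Nprl3, on chromosome 11 from 32225628 to 32267707, contains the enhancers of the alpha-globin genes and had shared peaks in introns 2, 6, 8 and 9. Scores reached 79 in replicate 1 and 98 in replicate 2 at 32238556 to 32238705 in intron 8. The peaks in introns 8 and 9 lay within 1 kb of an annotated protein-coding TSS, so they were not counted as distal. The globin genes Hba-x and Hbb-bh1 had 0 shared peaks in their territories, and Hbb-y had 1, on chromosome 7 at 103861056 to 103861205 (scores 63 and 69). Alb had 2 peaks in its territory, of which 1 lay in the gene, 6.55 kb from the TSS (scores 82 and 86), and Afp had 3 in its gene body. The promoter peak counted for Afp lay at the start of a shorter annotated transcript inside the gene, and its 5'-most TSS had none. Myh6, a cardiac myosin gene, had 1 peak and Pou5f1, a pluripotency gene, had 2, and neither had a promoter peak in either replicate.

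The replicates were next compared list by list for promoters with a peak in only 1 of them. In 24 lists at most 3 promoters were of this kind, for which the exact binomial test cannot give an unadjusted p below 0.25, so it tells nothing about them. The smallest adjusted p was 1 by that exact test and 0.759 by Fisher's exact test against all other genes. Unadjusted, 0 lists passed the threshold of 0.05 by the binomial test and 1 by Fisher's test. The list that passed was the receptor genes, the only one the binomial test could call, with 19 seen only in replicate 1 and 19 only in replicate 2, while over all genes the numbers were 190 and 390. Taking the same number of best-scoring peaks from each library kept all peaks of replicate 1 and removed the lowest-scoring peaks of replicate 2. In that setting 27 receptor genes had a promoter peak only in replicate 1 and 2 only in replicate 2. The adjusted p was 4.06e-05 by the exact binomial test and 3.51e-05 by Fisher's exact test, and over all genes the numbers were 268 and 247. With a promoter window of 2500 bp the receptor numbers were 35 and 59, in the other direction (adjusted p = 0.430 by the exact binomial test). All genes leaned the same way with that window, at 259 and 476. These tests compare 2 libraries, not conditions.

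Sequence motifs of several transcription factor families were enriched in distal peaks over windows 1 kb to either side. The CTCF consensus, bound by the insulator protein CTCF, occurred in 5.03% of 125474 distal peaks. Ratios were taken over 223681 pairs of a peak and a flank free of peaks, in which the CTCF share was 5.31% in peaks, 160 times that in flanks. REST, a repressor of neuronal genes, was rarer (0.253% of distal peaks) and over the pairs (0.272% of peaks) 608 times its share in flanks, where it occurred 1 time, so its ratio is loose, at 121 with flanks at 5 kb, 315 without replicate 1 and 311 without replicate 2. The RFX motif was 22.5 times, NFI 17.9 times, NRF1 4.59 times, SP-KLF 3.89 times, ETS 3.39 times and the E-box CAGCTG, which proneural and muscle regulators bind, 2.95 times as frequent as in flanks, and CAGCTG was in 18.5% of distal peaks. Smaller ratios were seen for TEAD (1.80), the E-box CAGATG (1.68), SOX (1.62), AP1 (1.45) and NFY (1.43). The ratios of rare motifs varied with the setting, with CTCF at 125 without replicate 2 and 255 in the better-scoring 50%, NFI at 11.9 without replicate 1 and NRF1 at 9.29 with flanks at 5 kb. The 13 motifs passed the exact binomial test on discordant pairs after adjustment over 18 motifs, the largest adjusted p being 9.17e-19, for NRF1. Most peaks entered with both flanks, so the pairs are not independent and the exact p values of the motifs are too small.

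The motifs of GATA (0.652), homeobox (0.719) and MEF2 (0.355) factors were less frequent in distal peaks than in flanks, the largest adjusted p of the exact test being 5.03e-71, for GATA. HNF4 (ratio 0.923, adjusted p = 0.274) and FOX (0.999, adjusted p = 1) did not pass the exact test, but with flanks at 5 kb HNF4 was called less frequent (0.811, adjusted exact p = 0.00111). In pairs of peak and flank with GC content within 2 percentage points, the ratios were 2.03 for homeobox, 1.24 for MEF2, 1.71 for FOX and 0.874 for GATA, and 117 for CTCF. In the same pairs SP-KLF fell to 1.46 and the E-box CAGCTG was in 16.6% of peaks and 8.49% of flanks, a smaller ratio than over all pairs, and ETS (1.61, adjusted exact p = 0.0639) and NRF1 (3.25, adjusted exact p = 0.0552) no longer passed. Against the reversed consensus in the same peaks, homeobox (1.17) and MEF2 (1.5) were above 1 and ETS (0.572) below 1.

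**Figure D4:**
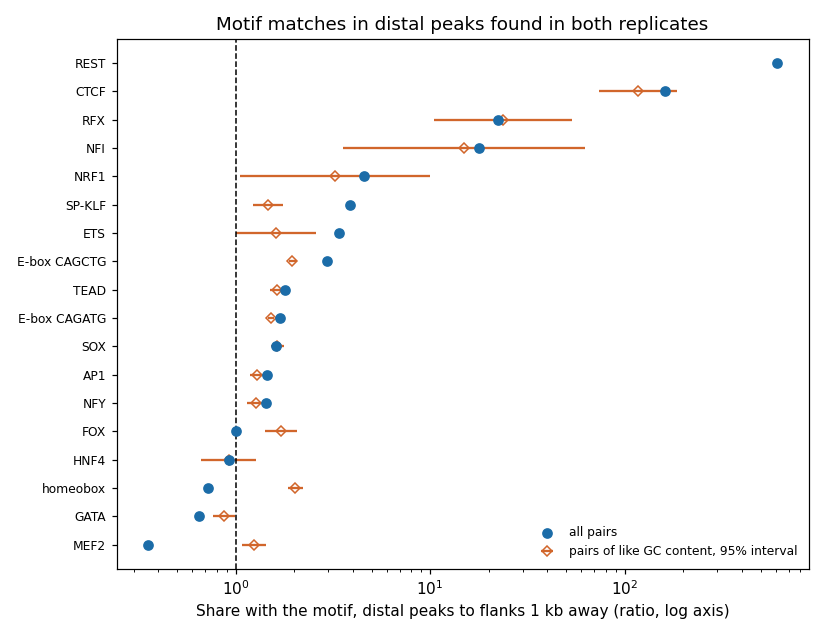
Ratio of the share of distal peaks with a motif to the share of flanking windows with it, over pairs of both (horizontal log axis) for 18 motifs, in all pairs (filled points) and in pairs of like GC content (open diamonds, with 95% intervals, not drawn for REST, whose matched flanks had no match). Homeobox moves from 0.719 to 2.03 and MEF2 from 0.355 to 1.24, while CTCF is at 160 and 117.

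Peak density differed between the X chromosome and the autosomes in these embryos of both sexes. Replicate 1 had 29.9 peaks per Mb on X and 83.3 on the autosomes, and replicate 2 had 34.5 and 94.0. The ratio was 0.363 ± 0.0051 (SD, n = 2), so the gap was far larger than the spread between replicates, and no test was run on it. Autosomes ranged from 68.3 per Mb on chromosome 14 to 114 on chromosome 11 in replicate 1 and from 79.1 to 128 on the same chromosomes in replicate 2. The Y chromosome had 0.443 and 0.647 peaks per Mb. Counted per protein-coding gene the X to autosome ratio was 0.543, and among the better-scoring 50% of peaks it was 0.256 per Mb.

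**Figure D5:**
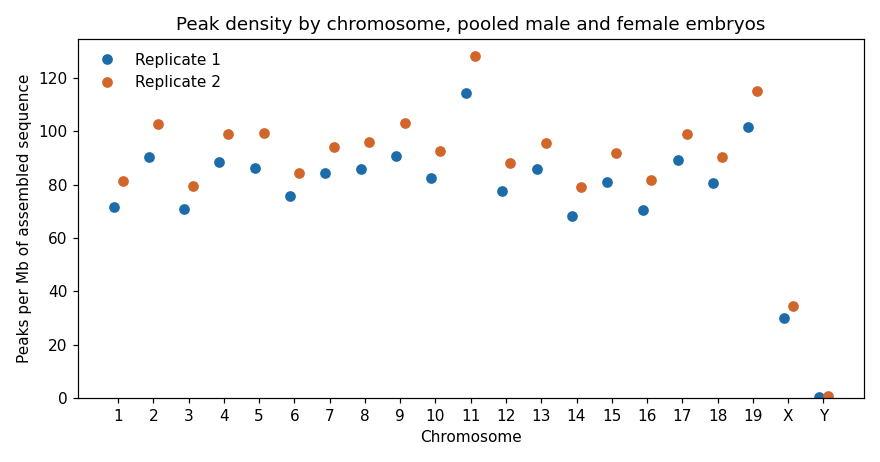
Peaks per Mb of assembled sequence (vertical axis) on each chromosome (horizontal axis), with 1 point per replicate. The autosomes lie between 68.3 and 128 per Mb, X at 29.9 and 34.5 and Y at 0.443 and 0.647.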

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

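The ratio per gene on X and the CpG match of single lists were planned as alternatives, but their use as tests of an explanation, the tests on pooled lists and on receptor genes and the share of X promoters were chosen after the results they bear on had been seen. No biological explanation was tested for any pattern, since there is 1 group only.

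Signals stood outside the chromosomes used for the comparisons. The mitochondrial genome, which has no nucleosomes, had 26 peaks in replicate 1 and 32 in replicate 2, with scores of at least 121 and 120. Of these, 10 and 13 had the top score of 150, and 26 and 27 were shared. Unplaced and unlocalised scaffolds held 212 peaks on 26 sequences in replicate 1 and 168 on 21 in replicate 2, of which 135 and 129 were shared.

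The X chromosome had 0.363 times the peak density of the autosomes. Fewer genes do not account for it alone, because the ratio per protein-coding gene was still 0.543 ± 0.0076 (SD, n = 2), and repeats, which make up 46.8% of X and 33.5% of the autosomes, do not either, because outside repeats the ratio was 0.434 ± 0.0038. Fewer X copies in a pool of both sexes are not excluded: the median score of X promoter peaks was 108 in replicate 1 and 113 in replicate 2, below the ranges of autosomal promoter sets of like CpG content (116 to 122 and 122 to 128), a mean ratio of 0.906. The score has no known zero and only promoters with a peak enter, so that ratio gives no copy fraction, and the silenced X of female embryos would lower scores too. Of 948 X genes 52.3% had a shared promoter peak, against 64.1% (95% range 61.9 to 66.2) in autosomal sets of like CpG content, a smaller shortfall than in density, and what produced the density gap was not measured.

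The GATA, homeobox and MEF2 motifs were less frequent in distal peaks than in their flanks, and mean GC content was 51.5% in peaks and 44.2% in flanks. In the 33633 of 223681 pairs with GC content within 2 percentage points, homeobox matches were 2.03 times as frequent in peaks (95% interval 1.86 to 2.22) and MEF2 matches 1.24 times (1.08 to 1.44), so GC content may account for their shortfall over all pairs. For GATA the matched ratio was 0.874 (0.769 to 0.992), higher than 0.652 over all pairs and with an interval that reaches the bound of 0.95 set for the test, so whether GC content explains the rest stays open. The matched pairs are 1 part of the peaks, and the other pairs were not tested in this way. A peak could enter with both flanks, so these intervals may be too narrow.

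Most promoter calls of the lists were lost under CpG matching, where lists already at 100% had little room for a call. Single lists were mostly not told from matched genes, while pooled lists lay outside the ranges of sets matched on CpG decile at the 5'-most TSS. Sets for pooled lists held no receptor gene, unlike those for single lists, so both matches are not alike. For the receptor list this raised the matched value from 16.9% to 21.2%, which widens a shortfall. CpG differences within a decile or at other TSSs were not matched, so their part in the remaining gaps is not excluded. The 8 lists called more often had promoter peaks at 96.0% of 151 genes, against 89.1% in matched sets (95% range 84.8 to 92.7), the 6 called less often at 27.8% of 90 genes against 41.1% (32.2 to 50), and receptor genes at 1.98% against 21.2% (19.2 to 23.3). Because these pools were picked by their calls, the sets were also formed without regard to the call. The 13 lists of embryonic tissues then had 82.9% of 199 genes against 75.9% (71.4 to 80.4), and the 7 lists of other cell types and organs had 35.0% of 103 genes against 50.5% (41.7 to 58.3).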

How the results depend on the processing

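Of 62 values of the comparisons under other settings, 42 kept their main value within the spread between replicates or, for counts, within 1.5 times, and 20 moved. For overlaps that spread was the SD of both directions, which is no spread of independent measurements. Among single lists and motifs, 420 of 488 kept their direction and side of the threshold. Shared peaks rose to 84.7% in the better-scoring 50%, and shared hotspots were 62.5% with reciprocal overlap of 50%. The promoter share of peaks was 22.8% and 29.9% with windows of 1000 and 2500 bp, which is 6.16-fold and 3.72-fold over the share of bases. It was 19.8% with all annotated genes, 26.0% in the better-scoring 50% and 14.2 to 15.4% with either replicate left out. Lists with promoter peaks more often numbered 4 with the 5'-most TSS alone, 4 without receptor genes in the background and 0 with CpG-matched genes, and lists less often numbered 1 with CpG-matched genes. Lists already at 100% had little room for a call in that match. CpG matching reversed erythroid (12.5 percentage points above matched genes), trophoblast (7.14 above) and Hox genes (-2.56). Lists with fewer distal peaks numbered 0 beyond 5 kb and in the better-scoring 50%, where random medians of 0 left both lower lists no room for a call, 1 by list means and 1 to 2 with either replicate left out. The match on territory length and CpG content together, chosen after seeing the data, left 11 lists with more distal peaks, losing neural crest (adjusted permutation p = 0.0567) and gut (0.0577), and, for the same reason, 0 with fewer. Beyond 5 kb imprinted genes fell to percentile 28.9 of their random lists. With equal list lengths 1 list differed between replicates. Against the reversed consensus, homeobox (1.17), HNF4 (1.42) and MEF2 (1.5) turned above 1 and ETS (0.572) below; SP-KLF reads the same reversed, so that setting is void for it, and REST gave no ratio there or in the better-scoring 50% for lack of matches in the comparison. The X to autosome ratio was 0.256 in the better-scoring 50% and 0.543 per gene. Except where a setting itself removes the peaks or genes in question, the cause was not tested. Genes with a promoter peak ranged from 14166 to 16301, lists with more distal peaks from 9 to 15 and enriched motifs from 12 to 13. The unknown depth limits what an unshared peak means. No paired analysis was possible because there is 1 group.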

Other observations

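The families and windows described here, and their boundaries, were chosen after seeing the data, and their values have no test.

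The shares of promoter peaks below stand against 70.3% of all protein-coding genes. All 19 Sox genes had a promoter peak in both replicates, as did all 8 Lhx, 6 Dlx and 6 Irx genes, with 8 of 9 Pax, 37 of 44 Fox and 10 of 13 Tbx genes. The median density of distal peaks was 15.4 per 100 kb for Dlx genes, which pattern the forebrain and face, 12.9 for Tbx genes and 10.1 for Sox genes, against 4.12 for all protein-coding genes. The median CpG ratio of these transcription factor families ran from 0.512 (Tbx) to 0.783 (Irx), within deciles where 87.0% to 99.2% of all genes had a promoter peak. Among ligands, 15 of 19 Wnt, 19 of 22 Fgf and 10 of 12 Bmp genes had a shared promoter peak. Zinc finger genes of the Zfp series had promoter peaks in 322 of 365 cases but a median of only 2.58 distal peaks per 100 kb. Ribosomal protein genes (88 of 98) and proteasome genes (38 of 39) had medians of 5.24 and 4.52. Promoter peaks were found in 14 of 49 keratin, 3 of 27 kallikrein, 4 of 42 beta-defensin and 0 of 22 major urinary protein genes. The median CpG ratio was 0.0930 for kallikreins, in a decile where 8.93% of all genes had one, and 0.116 for beta-defensins and 0.129 for major urinary proteins, in a decile with 21.2%. Keratins, at 0.323, fell in a decile with 58.2%. Clustered protocadherins, whose promoters are chosen cell by cell in neurons, had promoter peaks in 32 of 56 cases (57.1%). Their median CpG ratio of 0.557 fell in a decile with 87.0%.

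The Hox clusters differed in peak density. From the first to the last gene, Hoxa held 67 shared peaks over 105 kb (63.6 per 100 kb), Hoxb 98 over 174 kb (56.3), Hoxd 39 over 96.8 kb (40.3) and Hoxc 29 over 116 kb (25.1). Among 2625 windows of 1 Mb, with a median of 45 distal shared peaks, the highest count was 212, on chromosome 11 from 96000001 to 97000000, which holds Hoxb. The next were 197 on chromosome 8 from 120000001, at Gse1 and Irf8, and 173 on chromosome 5 from 111000001, at Mn1 and Pitpnb. The window after that at Gse1, from 121000001, had 160 and holds Foxf1, Foxc2 and Foxl1. A count of 169 was found on chromosome 13 from 23000001, in a cluster of histone genes, and 162 on chromosome 6 from 52000001, which holds Hoxa. In 105 windows there were 0.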
